A study of Arabidopsis thaliana with 3 samples.

How the data were processed

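Biotin-labelled cRNA from whole Arabidopsis thaliana seedlings was hybridised to Affymetrix oligonucleotide arrays, 1 array for each of 3 genotypes: wild type of the Columbia ecotype, the overexpressing line 35S:WRKY6-9 (35S:WRKY6 below), in which WRKY6 is driven by the 35S promoter, and the wrky6-1 knockout. Per the labels' protocols, seeds were kept in the cold for 2 days, germinated on MS agar at 22 °C under continuous light of 40 µmol per square metre per second, and harvested at 7 days, and 8 µg of purified total RNA was labelled per array. The groups were taken from the genotype and title labels. With 1 array per genotype there was no replicate, so no test was run, no p-value or standard error is given, and every difference is one between single arrays. No pairing between arrays was used.

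The values used were the deposited signal intensity per probe set on a linear scale, one column per array. The submitters' processing notes name GCOS 1.0 and MAS5, without saying which step each was used for. The 2% trimmed means of the deposited intensity values were 500.0 in wild type, 499.8 in 35S:WRKY6 and 500.1 in wrky6-1, so the arrays had already been scaled and were used without further scaling. The table held 22810 probe sets, of which 64 were Affymetrix controls that were left out of all comparisons of genes. Present or absent calls and probe-level values were not used here. Background subtraction makes low intensities imprecise, and a ratio of 2 low values is dominated by that imprecision. Values below the 30th percentile of the 22746 Arabidopsis probe sets over the 3 arrays, a signal of 45.5, were therefore raised to that floor before log2 ratios were taken. A fold against a value under the floor is a lower bound and is written "at least".

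A probe set was counted as measured in a comparison where the higher of the 2 arrays reached the pooled 50th percentile, a signal of 174.6. A probe set under that signal in wild type is therefore measured only where it is higher in the line, so the filter fixes its direction. Probe sets with a log2 ratio of 1 or more in size, which is 2-fold, were counted. For each fixed gene list and symbol family the median log2 ratio of its measured members was set beside 10000 random lists of the same size matched on mean log2 signal in 20 bins. That percentile was computed where at least 3 members were measured and describes these arrays only. Where a gene had several probe sets, the brightest one naming that gene alone was used. As the only available measure of precision within an array, the disagreement between probe sets of the same gene was computed. From 45, 47 and 46 genes the SD of a single probe set's log2 ratio was 0.25 for 35S:WRKY6 against wild type, 0.23 for wrky6-1 against wild type and 0.28 between the lines. It leaves out differences between plants, extractions and hybridisations. The number of arrays limits the precision of every value.

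Both lines were compared with the same wild-type array, so chance deviations of that array enter both ratios. Unchanged arrays sharing 1 control were simulated 200 times, with residuals drawn by signal from the difference between the 2 lines, which also contains any real difference between them. Residuals were drawn separately for each array, so a probe set that varies more than others of similar signal was not represented. Counts shared by both lines are given beside the simulated counts and beside the number that independent lists of the same lengths would share. Because there is 1 wild-type array, the control could not be split.

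Probe sets were named from the platform annotation table and updated through Entrez identifiers to the TAIR10.1 gene table, to which 13436 matched. A single gene was named for 13513 probe sets and several genes for 503, which were not named here. The other 8730, or 38.4%, were not listed in the annotation used here. A gene symbol was carried by 1580 of the single-gene probe sets and the other 11933 had only a locus code. PHO1, the phosphate exporter gene known as a WRKY6 target, was to be reported with WRKY6, but no named probe set for it was analysed here. No coordinates are given, because neither the labels nor the data table name a genome build, and TAIR10.1 was used only for names and for which genes are neighbours.

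Before the data were examined, the comparisons, the floor, the filter, the thresholds, 19 gene lists, the alternatives and the rule for naming genes were fixed. The rule took WRKY6, the 8 largest rises and the 8 largest falls in each comparison with wild type among genes with a symbol, the 2 measured members of each list with the largest log2 ratio in size, and up to 6 genes per direction that moved oppositely in the 2 lines. A symbol was taken to mean one other than the locus code, and list members without such a symbol were kept under their locus code. Both readings were settled after the annotation was seen. The groups for leucine breakdown, the ATG8 family and plastid-encoded genes, the scan of symbol families, the details of the simulation and the use of the same-gene SD as a tolerance were chosen after the data were seen. The leucine and ATG8 groups followed from seeing MCCA, IVD, AKINBETA1 and ATG8F among the large changes and from an informal look at remembered dark, starvation and shade genes. Alternatives were quantile, median and lowess scaling (lowess fraction 0.3), floors at the 20th and 40th percentiles or none, no filter, a filter at the 70th percentile or on the mean of 3 arrays, probe sets naming 1 gene only, and thresholds of 1.5-fold and 3-fold.

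The counting step was tested on simulated data for 35S:WRKY6 against wild type with a spread of 0.2 log2 units, in which 11723 probe sets were measured. It called 99.0% of 100 probe sets changed 4-fold, 3.0% of 100 changed 1.5-fold, and 5 of 11525 unchanged ones. The measured log2 ratios of that comparison on the real arrays had an SD of 0.64, real changes included. The simulated shares are therefore not error rates of the counts below. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.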

Results

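Transcript levels were measured on 3 arrays, 1 each from 7-day-old wild-type seedlings, seedlings of the line 35S:WRKY6-9, which overexpresses the transcription factor WRKY6 and is called 35S:WRKY6 below, and seedlings of the knockout wrky6-1. The design asks which genes depend on WRKY6. No genotype was replicated, so each fold below is a ratio of single arrays with no replicate check and no p-value. The median signal was 182 in wild type, 169 in 35S:WRKY6 and 173 in wrky6-1, and 29.8%, 30.3% and 29.9% of Arabidopsis probe sets lay below the floor. The ratio of 3' to 5' probe sets of actin, a measure of RNA integrity, was 1.97, 1.89 and 1.84 on the same arrays by the later control probe sets and 10.2, 13.1 and 9.16 by the earlier ones. For GAPDH it was 0.952, 0.893 and 0.923 by the later and 1.23, 1.25 and 0.953 by the earlier ones. For ubiquitin it was 1.17, 0.994 and 1.12 by the later and 2.66, 2.09 and 1.87 by the earlier ones. The 25S ribosomal RNA control had a signal of 310, 152 and 65.2. Across probe sets, which are not independent replicates, log2 signals had a Pearson r of 0.968 between wild type and 35S:WRKY6, 0.961 between wild type and wrky6-1 and 0.970 between the lines.

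The WRKY6 transcript itself (AT1G62300, chromosome 1) had a signal of 322 in wild type, 9245 in 35S:WRKY6 and 12.1 in wrky6-1. It was 28.7-fold higher in 35S:WRKY6 than in wild type (log2 ratio 4.84). In wrky6-1 it lay under the floor and was at least 7.08-fold lower than in wild type (log2 ratio -2.82). Both directions match the labels. Where the probe set lies relative to the insertion was not analysed here, so the knockout value alone is a limited check of that label.

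In 35S:WRKY6 the β-glucosidase genes BGLU28 and BGLU19 had higher signals than in wild type. BGLU28 was 814 against 65.1, 12.5-fold higher, and BGLU19 was 316 against 61.6, 5.13-fold higher. PUB19, a U-box ubiquitin ligase, was 10.4-fold higher (1435 against 138), and ICL, the isocitrate lyase of the glyoxylate cycle, was at least 7.89-fold higher (359 against 31.8). The cytokinin response regulator RR16 was 5.88-fold higher. The late embryogenesis abundant protein genes LEA18 and LEA4-5 were at least 5.28-fold and 5.04-fold higher. Among the genes with lower signals, IAA29, an Aux/IAA repressor of auxin responses, had a signal of 54.0 against 865, a log2 ratio of -4.00. WES1, which encodes an enzyme that conjugates auxin to amino acids, was 9.71-fold lower (441 against 4287). EXPA16, an expansin, was 8.81-fold lower (156 against 1379). MCCA, a subunit of the methylcrotonoyl-CoA carboxylase of leucine breakdown, was 6.03-fold lower. Another WRKY factor, WRKY47, went from 254 to 40.7, at least 5.58-fold lower, while it was 355 in wrky6-1. The AP2/ERF factor gene ORA47 was 5.47-fold lower. FHL, which acts in nuclear import of phytochrome A, was 5.28-fold lower, and the glycosyltransferase gene UGT73B1 was 5.22-fold lower.

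Of 12139 probe sets measured in 35S:WRKY6 or wild type, 460 were at least 2-fold higher and 681 at least 2-fold lower in 35S:WRKY6. Together these 1141 were 9.40% of those measured. Of them, 608 named 1 gene and 100 carried a symbol, so the genes named here cover a small part of the changed probe sets.

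Among the lists with at least 3 measured members, flavonoid and anthocyanin synthesis had the largest shift in wrky6-1. DFR, the dihydroflavonol reductase that leads to anthocyanins, had a signal of 1053 against 83.9 in wild type, 12.6-fold higher. The anthocyanin glycosyltransferase gene UF3GT was 12.5-fold higher (864 against 69.0), AT4G14090 was 9.86-fold higher (846 against 85.8), and the anthocyanin malonyltransferase gene AT5MAT was at least 7.48-fold higher (340 against 16.9). The list of 15 pigment genes had 4 members with a named probe set. All 4 were measured and at least 2-fold higher, with a median log2 ratio of 3.47 at the 100th percentile of matched random lists. AT4G14090 was outside the naming rule and was named after its value was seen, to complete the 4. UGT78D1, a flavonol rhamnosyltransferase outside the list, was 7.61-fold higher (1657 against 218), with a log2 ratio of 0.94 in 35S:WRKY6 (416). All 4 listed genes had wild-type signals under the filter, but none with a probe set was left out by it. In 35S:WRKY6 their ratios to wild type went both ways, with log2 ratios of 1.44 for DFR, the only one measured, 0.93 for UF3GT and -0.31 for AT4G14090, and AT5MAT under the floor on both arrays.

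Other genes with higher signals in wrky6-1 were SAG29, a sugar transporter known from senescing leaves, at 883 against 64.4 (13.7-fold), and TBL26 at 1246 against 108 (11.5-fold). LEA4-5 was 6.83-fold and HOS3-1 6.50-fold higher. SAG29 was also higher in 35S:WRKY6, at 264, a log2 ratio of 2.03. The lower signals in wrky6-1 included IAA29, at least 19.0-fold lower at 31.4, and the cold-regulated gene COR27, 11.9-fold lower (64.2 against 761). SIS was 9.48-fold lower (358 against 3395), and the linker histone gene HIS1-3 was 9.44-fold lower (137 against 1291). MCCA was 8.38-fold lower (355 against 2980), and AKINBETA1, a regulatory subunit of the energy-sensing kinase SnRK1, was 8.28-fold lower (378 against 3126). FHL was at least 7.11-fold lower (38.5 against 323). Of 12222 measured probe sets, 631 were at least 2-fold higher and 950 at least 2-fold lower in wrky6-1. These 1581 were 12.9% of those measured, 810 of them named 1 gene, and 133 carried a symbol.

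**Figure D1:**
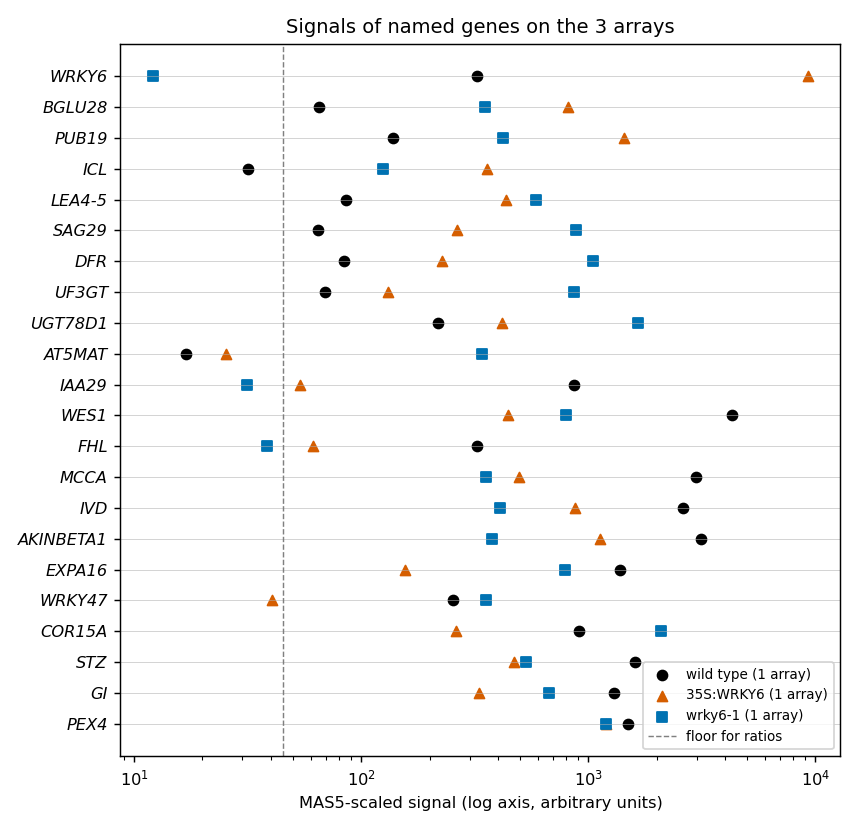
Deposited MAS5-scaled signal (log axis) of 22 named genes on the 3 arrays, each point being 1 array and the dashed line the floor used for ratios. WRKY6 spans 12.1 in wrky6-1 to 9245 in 35S:WRKY6, and IAA29, WES1, FHL, MCCA, IVD, AKINBETA1 and STZ lie lower in both lines than in wild type.

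Many named genes lay on the same side of wild type in both lines. Leaving out WRKY6, 6 of the 8 named falls in 35S:WRKY6 were also at least 2-fold lower in wrky6-1. Of the named falls in wrky6-1, 7 of the 7 were also at least 2-fold lower in 35S:WRKY6. Among all probe sets, 382 of the 681 falls in 35S:WRKY6 and of the 950 in wrky6-1 were at least 2-fold lower in both lines. The named falls were picked by their ratio to the shared wild-type array, so a high value there alone would lower both ratios. IAA29, FHL and MCCA stood among the largest falls of both comparisons. All 7 named rises in 35S:WRKY6 and 7 of the 8 in wrky6-1 had wild-type signals under the filter, so they are given without it. By their floored ratios 4 of the 7 and 4 of the 8 were at least 2-fold higher in the other line, while RR16, LEA18 and BGLU19 in wrky6-1 and TBL26, UF3GT, AT5MAT and UGT78D1 in 35S:WRKY6 were not. Over the 11856 probe sets measured in both comparisons, 382 were at least 2-fold lower in both lines. The simulation of unchanged lines sharing the wild-type array gave a median of 204.5 (167 to 238), and independent lists would share 54.6. Control probe sets, which were left out of the 382, went both ways. The 25S ribosomal RNA control was lower in both lines, at 152 in 35S:WRKY6 and 65.2 in wrky6-1 against 310 in wild type. The later 3' GAPDH control was higher in both, at 13734 and 14413 against 12576. For probe sets higher in both lines the count was 139, the simulated median 151 (122 to 185) and the independent lists' count 14.9. The log2 ratios had a Pearson r across probe sets of 0.626, against 0.534 (0.502 to 0.563) in the simulation, and a covariance of 0.269 against 0.190 (0.173 to 0.205), a difference of 0.0796. Part of the excess may come from the shared control, which 1 array does not allow to be separated. The simulation also left out probe sets more variable than others of similar signal, so its counts may be too low. Any real difference between the lines is in its residuals and would make its counts too high.

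**Figure D2:**
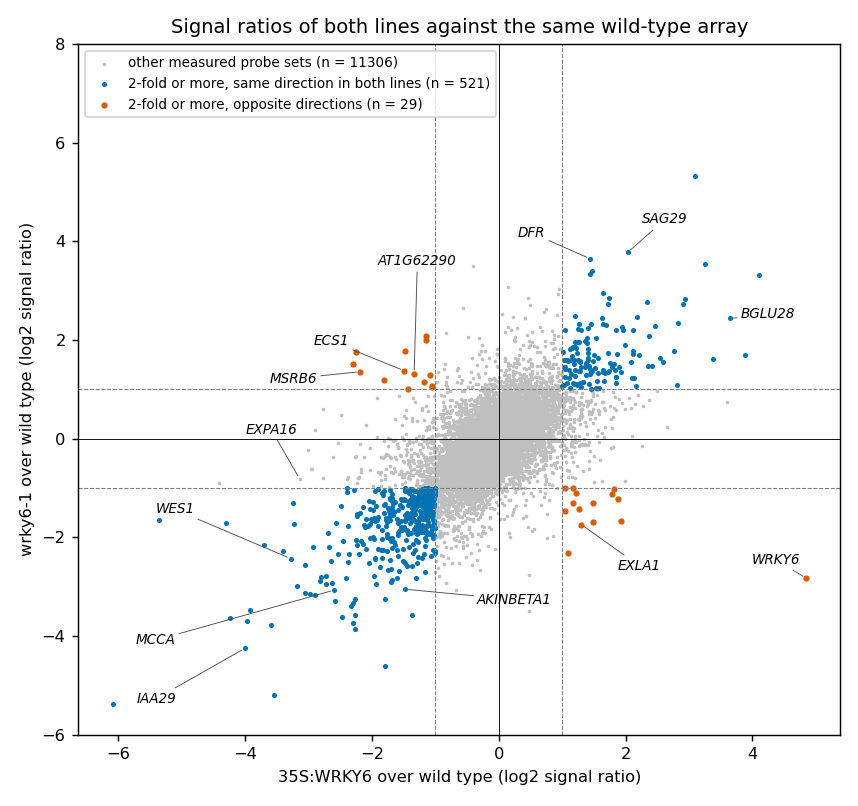
Log2 signal ratio of 35S:WRKY6 (horizontal axis) and wrky6-1 (vertical axis) to the same wild-type array for the 11856 probe sets measured in both comparisons, with dashed lines at 2-fold. At 2-fold or more 521 probe sets lay on the same side of wild type in both lines (simulated median for unchanged lines sharing that array 359, range 295 to 406) and 29 on opposite sides (6, range 0 to 14), and WRKY6 is the point at the lower right.

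A gene that follows the WRKY6 dose would move oppositely in the lines. At the 2-fold threshold 15 probe sets were higher in 35S:WRKY6 and lower in wrky6-1, and 14 were lower in 35S:WRKY6 and higher in wrky6-1. The simulation gave a median of 3 for each (at most 8 and 9), and independent lists would share 27.8 and 29.2. Under lowess scaling the 14 became 9, not above the highest count simulated without that scaling. Because the simulation left out probe sets more variable than others of similar signal, its counts may be too low. Its residuals also contain any real difference between the lines, which would make its counts too high. Higher with overexpression and lower in the knockout were, besides WRKY6, the expansin-like gene EXLA1 (690 in wild type, 1702 in 35S:WRKY6 and 207 in wrky6-1), the serine carboxypeptidase-like gene SCPL34 (928, 2233 and 343), AT1G15010 (233, 890 and 72.8) and AT5G26200 (316, 712 and 128). These were all 5 genes named by a single-gene probe set in that direction. In the other direction 9 probe sets named 1 gene. The 6 with the largest values of the smaller of their 2 log2 ratios in size were AT5G55450 (224, 7.46 and 642), AT3G44450 (243, 87.7 and 837), ECS1 (5517, 1959 and 14374), MSRB6, a methionine sulfoxide reductase (415, 91.2 and 1063), AT1G62290 (505, 201 and 1260) and the cold-induced chloroplast protein gene COR15A (913, 261 and 2081). COR15A was 3.50-fold lower in 35S:WRKY6 and 2.28-fold higher in wrky6-1.

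Compared directly, 35S:WRKY6 and wrky6-1 differed by at least 203-fold in WRKY6 (log2 ratio 7.67). Of 12000 measured probe sets, 543 were at least 2-fold higher and 558 at least 2-fold lower in 35S:WRKY6 than in wrky6-1. All 4 flavonoid genes were lower in 35S:WRKY6 than in wrky6-1, with a median log2 ratio of -2.81 below every matched random list. UF3GT, AT4G14090 and AT5MAT, at 132, 69.1 and 25.4 in 35S:WRKY6, were measured only through wrky6-1, so the filter fixed their direction. DFR differed 4.63-fold between the lines and UF3GT 6.57-fold. The 3 root-expressed genes had a median of 0.65, at percentile 95.9, which was -0.06 under the 70th-percentile filter and 0.30 under the filter on the mean. The 3 photosynthesis genes had a median of -0.01.

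The remaining lists had few named probe sets, and each list covered under 80% of its members. The PHO1 family had 7 of 11 genes with a probe set and 2 measured. AT2G03240 had a signal of 353 in wild type, 171 in 35S:WRKY6, 2.06-fold lower, and 332 in wrky6-1, and AT1G35350 had log2 ratios of 0.14 and -0.19. The lists of PHT1 phosphate transporters, phosphate starvation genes and boron transporters had 0 members with a named probe set here. Of the 66 WRKY genes, 7 had a probe set and 5 were measured. Their median log2 ratios were -0.02 in 35S:WRKY6 (percentile 58.1), -0.03 in wrky6-1 (percentile 53.5) and 0.01 between the lines. The first 2 medians turned slightly positive under quantile and lowess scaling. With fewer members left by the 70th-percentile filter they were 2.37, 0.14 and 3.71, and by the filter on the mean 0.26, -0.95 and 1.2. WRKY22 was 3.65-fold lower in wrky6-1 (77.4 against 282), with a log2 ratio of 0.53 in 35S:WRKY6.

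The 3 measured of 24 photosynthesis genes went both ways and had median log2 ratios of -0.04 in 35S:WRKY6 and 0.05 in wrky6-1, the second turning negative under quantile and lowess scaling. RCA, which encodes Rubisco activase, had ratios of 0.34 and 0.35, and the light-harvesting gene LHCB4.2 had -0.40 and -0.47. The 3 measured of 18 root genes, listed as markers of the share of root in a whole seedling, had a median of 0.77 in 35S:WRKY6 (percentile 98.1), and 0.30 under the 70th-percentile filter. Whether they reflect that share here was not tested. The root hair expansins EXPA7 and EXPA18 were at 0.92 and 0.77 and PYK10 at 0.30, none reaching 2-fold, and EXPA7, at 128 in wild type, passed the filter only through its signal in 35S:WRKY6. In wrky6-1 EXPA18 was at 0.13 and PYK10 at 0.36. The reference genes, 3 of 9 with a probe set, had medians of -0.02 in 35S:WRKY6, slightly above 0 under each other scaling, -0.32 in wrky6-1 and 0.26 between the lines. PEX4 was at -0.32 in both lines, AT2G28390 at 0.37 in 35S:WRKY6, and AT4G34270 at -0.32 in wrky6-1.

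Several lists had a single measured member. SAG29 was that of the 16 senescence genes. For the 17 touch and wounding genes it was the zinc finger gene STZ, 3.43-fold lower in 35S:WRKY6 and 3.04-fold lower in wrky6-1 (1611 in wild type, 470 and 531). For the 16 clock genes it was GI, 3.93-fold lower in 35S:WRKY6 (330 against 1297) with a log2 ratio of -0.95 in wrky6-1. For the 13 heat shock genes it was AT5G48570, 2.72-fold higher in 35S:WRKY6 with a log2 ratio of 0.74 in wrky6-1. For the 14 glucosinolate genes it was BCAT4, 2.42-fold higher in wrky6-1 with a log2 ratio of 0.22 in 35S:WRKY6. Of the 16 abscisic acid and dehydration genes 2 were measured: COR15A, given above, and the dehydrin gene COR47, with log2 ratios of -0.18 and -0.48. No member was measured of the 19 salicylate genes, the 19 jasmonate and ethylene genes, the 13 seed maturation genes or the 18 iron genes, which had 1, 2, 1 and 1 probe sets.

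**Figure D3:**
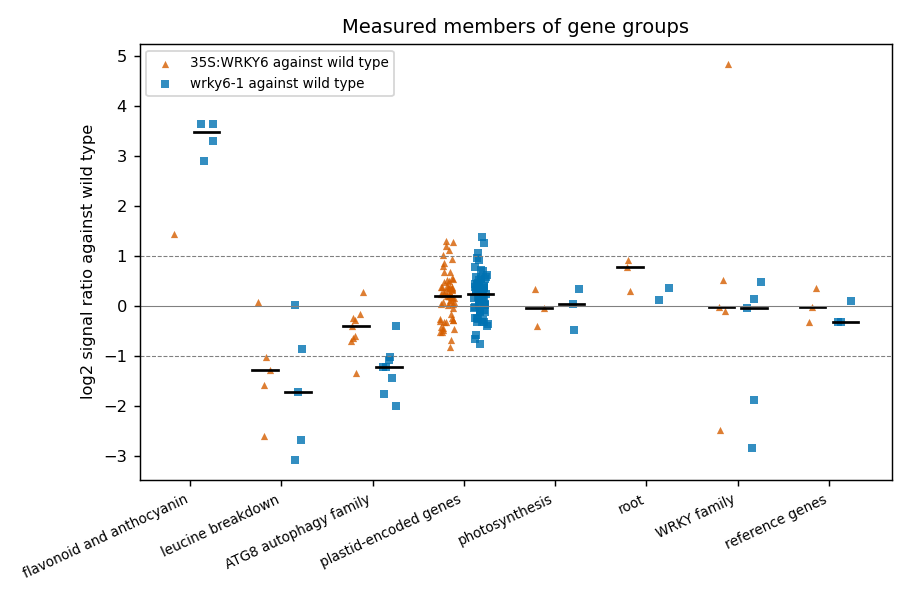
Log2 signal ratio to wild type of the measured members of 8 gene groups in 35S:WRKY6 (triangles) and wrky6-1 (squares), each point 1 gene on single arrays, with a bar at the median where at least 3 were measured and dashed lines at 2-fold. The 4 flavonoid genes lie at a median of 3.47 in wrky6-1, while the leucine breakdown, ATG8 and plastid-encoded groups were chosen after the data were seen.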

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

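The 2 tests of single probe sets and of scaling in the first pattern were set before their results were seen, though the simulation under each scaling was added later, and the other tests below were chosen afterwards.

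The control probe sets outside the gene comparisons gave a signal that differed between arrays. Hybridisation spike-ins, transcripts of fixed amount added to each sample, had a median ratio of 1.31 (range 1.17 to 1.39, 9 of 9 above 1) for 35S:WRKY6 over wild type, and 1.05 for wrky6-1 over wild type. The Bacillus spike-ins had medians of 0.867 and 0.966 over the 12 later probe sets and 1.003 and 0.981 over the 12 earlier ones, and on the 35S:WRKY6 array 9 other probe sets for the hybridisation controls were listed at exactly 0.

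The pattern that most calls for follow-up is the 382 probe sets lower in both lines, among them IAA29, MCCA, WES1 and FHL. Control probe sets, left out of the 382, went both ways. The 25S ribosomal RNA control was lower in both lines (310 in wild type, 152 in 35S:WRKY6 and 65.2 in wrky6-1). The later 3' GAPDH control was higher in both (12576, 13734 and 14413). Scaling or a trend with signal is argued against as the whole cause, since the count was 347, 364 and 333 under quantile, median and lowess scaling, where the highest simulated counts were 241, 243 and 239, and 319 of the original 382 were kept under lowess. Error of single probe sets on the wild-type array stays open: 1 gene had another probe set, which was not measured, and its value of -0.90 was set by the floor in both lines and decides nothing. A wild-type sample harvested in a more starved or darker state may also account for part of it, but has no independent test. The leucine breakdown and ATG8 groups, known to rise in the dark, together had medians of -0.61 in 35S:WRKY6 and -1.22 in wrky6-1. They were picked after some members were seen to be low. ATG8 alone was at -0.40 in 35S:WRKY6. Between the lines, 35S:WRKY6 was above wrky6-1 by a median log2 ratio of 0.74 for ATG8 (8 of 9 above 0) and 0.43 for leucine breakdown (4 of 5). A wild-type state alone would not give that difference. Handling and harvest time were not tested, STZ and GI being the only measured members of their lists. With 1 wild-type array a state of that sample cannot be told apart from a change common to both lines.

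The second pattern is the higher flavonoid and anthocyanin signal in wrky6-1. A low wild-type array alone is argued against, because wrky6-1 was also above 35S:WRKY6, by a median log2 ratio of 2.81 over the 4 genes (lowest 2.21), above all 10000 matched random lists between those arrays. Between the lines the filter fixed the direction of all but DFR, though it left out none of the 4. A graded response to WRKY6 stays open, since only 1 of the genes, DFR, was measured between 35S:WRKY6 and wild type, and the filter fixed its direction. The dim values went both ways, at 0.93 for UF3GT and -0.31 for AT4G14090. UGT78D1, outside the list, was above the filter in wild type (218) and in 35S:WRKY6 (416). Its log2 ratio there was 0.94, so it was higher in 35S:WRKY6 as well as in wrky6-1. It is 1 gene, picked for its rise in wrky6-1, and does not decide the question for the list. A loss of WRKY6 may raise these genes, but a difference in light, stress or harvest of the single wrky6-1 sample was not tested, and how far samples of one genotype differ is not known here.

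The third pattern is AT1G62290, the coding gene next to WRKY6, which was lower in 35S:WRKY6 and higher in wrky6-1. Cross-hybridisation of WRKY6 transcripts would raise its signal in 35S:WRKY6, where its log2 ratio was -1.33, and would not give its signal of 1260 in wrky6-1, where WRKY6 was at 12.1. The cause of the lower signal in 35S:WRKY6, a line not labelled as carrying the insertion, stays open: the -1.33 is what drew attention to the gene, and sample variation is not known. For the higher signal in wrky6-1 (log2 ratio 1.32), a local effect of the insertion could be the cause: the other 2 measured neighbours reached at most 0.44, but an insertion can act on the adjacent gene alone.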

How the results depend on the processing

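All alternatives here were fixed before the data were examined, leaving out an array was not possible with 1 per genotype, and the cause of a shift was not tested except where a filter or threshold changes what is counted. Of the counts, 82 stayed within 1.5 times their value and 38 did not. Of the 41 values of named genes past 2-fold, all 41 kept their sign under each scaling. Under lowess and under quantile scaling 40 stayed past 2-fold. The floors and filters could not change a sign, since a filter leaves the ratio as it was and each floor lies below the filter. Only 27 and 29 of the 41 values remained measured under the filters at the 70th percentile and on the mean. Of the list medians, 119 stayed within 0.1 log2 units and 24 did not, among them the WRKY and root medians under these filters. The share of lower among changed probe sets was 59.7% in 35S:WRKY6 and 60.1% in wrky6-1, and 50.4% and 53.7% under lowess. Scaling moved the median of measured ratios by under 0.1 log2 units.

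Counts follow in the order higher and lower in 35S:WRKY6, higher and lower in wrky6-1, higher and lower between the lines, the 2 opposite directions, and higher and lower in both lines. A threshold of 1.5-fold gave 1239, 1787, 1775, 2230, 1433, 1518, 52, 55, 512 and 1101. A threshold of 3-fold gave 167, 209, 200, 324, 157, 171, 2, 1, 32 and 101. Probe sets naming 1 gene gave 237, 371, 291, 519, 265, 269, 5, 9, 70 and 203, fewer being tested. The filter at the 70th percentile gave 283 and 414 in 35S:WRKY6, 334 and 326 between the lines, 7 and 7 in opposite directions and 74 higher in both. Lowess gave 9 in place of 14 lower in 35S:WRKY6 and higher in wrky6-1.

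The WRKY6 log2 ratio in wrky6-1, -2.82 because the knockout lay under the floor, was -4.73 with no floor, -4.03 and -1.74 with floors at the 20th and 40th percentiles and -2.19 under lowess. Between the lines it was 9.57, 8.87 and 6.58 with those floors. WRKY6 in wrky6-1 had no value under the 70th-percentile filter. Signals near the floor limit these folds to bounds.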

Other observations

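Everything in this part was chosen after the data were seen, and no explanation was tested here beyond those above.

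Most genes of the group built for leucine breakdown had lower signals in both lines, and most ATG8 autophagy genes had lower signals in wrky6-1. Both groups were built after some of their members were seen to be low, so their medians describe them and are not set against random lists. IVD, the isovaleryl-CoA dehydrogenase, had a signal of 2614 in wild type, 878 in 35S:WRKY6 and 410 in wrky6-1, and MCCB, the partner subunit of MCCA, had 1809, 750 and 555. ETFQO, which passes electrons from this breakdown to the respiratory chain, had 602, 298 and 333. D2HGDH, placed in the group but not itself a step of leucine breakdown, hardly differed, with 307, 326 and 312. The 5 genes of this group had a median log2 ratio of -1.27 in 35S:WRKY6 and -1.71 in wrky6-1. All 9 ATG8 genes, whose products coat autophagosomes, had a probe set. In wrky6-1, 7 of the 8 measured were at least 2-fold lower (median -1.21), led by ATG8F (6212 in wild type, 4100 in 35S:WRKY6 and 1554 in wrky6-1) and ATG8E (1269, 821 and 374). In 35S:WRKY6 1 of 9 was at least 2-fold lower, with a median of -0.40 and ATG8G higher (log2 ratio 0.28). Both groups kept their direction under quantile, median and lowess scaling. Outside these groups, the 25S ribosomal RNA control was lower in both lines, with a signal of 310 in wild type, 152 in 35S:WRKY6 and 65.2 in wrky6-1. The later 3' GAPDH control was higher in both (12576, 13734 and 14413).

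A scan of 29 symbol families with at least 5 measured genes in each comparison gave further groups, each with the direction given here under every scaling. The sugar transporters with a SWEET symbol had a median log2 ratio of 0.80 in wrky6-1 (7 measured, 2 at least 2-fold higher, percentile 99.96). In 35S:WRKY6 the median was 0.50 (6 measured, 1 at least 2-fold higher), where SWEET1 and SWEET11 had ratios of -0.76 and -0.48. SAG29, also named SWEET15, was left out by its symbol. It was higher in both lines, with log2 ratios of 3.78 in wrky6-1 and 2.03 in 35S:WRKY6. SWEET4 was 4.61-fold higher in wrky6-1 and 3.89-fold higher in 35S:WRKY6 (63.1 in wild type, 291 and 246), and SWEET13 was 3.77-fold higher in wrky6-1, both passing the filter only through their signals in the lines. The β-tubulins had a median of -0.81 in wrky6-1 over 5 genes, with TUB1 2.21-fold and TUB6 2.00-fold lower. TUB9 and TUB7 differed less, with log2 ratios of -0.24 and 0.02. In 35S:WRKY6 the median of the 5 β-tubulins was -0.40, with 0 at least 2-fold lower. Between the lines, the cell wall XTH family had a median of 1.02 higher in 35S:WRKY6 over 5 genes. XTH20 was 5.33-fold higher there (1000 against 187), and XTH32 went the other way, 4.72-fold lower (470 against 2221). In wild type XTH20 was at 209 and XTH32 at 401. Against wild type the XTH medians were 0.23 in 35S:WRKY6 and -0.15 in wrky6-1. The UGT glycosyltransferases had a median of -0.42 over 26 genes between the lines. The 29 families were scanned in both comparisons with wild type and between the lines, so some extreme percentiles arise by chance.

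Of 69 plastid-encoded genes 63 were measured, with median log2 ratios of 0.21 in 35S:WRKY6 (46 above 0) and 0.25 in wrky6-1 (44 above 0). Under lowess scaling the medians were 0.08 and 0.10. Of the 63, 5 and 3 were at least 2-fold higher and none of those measured was 2-fold lower.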
